A study of Mus musculus with 2 samples.

How the data were processed

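Total RNA was sequenced from 2 pools of embryonic mouse kidney, both of the only group, embryonic kidney, with 10 ng of RNA as input to each library, per the labels. Per the labels, RNA was extracted with the mirVana method, fragments longer than 200 nt were measured, spike-in RNAs were added, and a manual for a low-input SMARTer kit is listed among the protocols. The spike-in rows of the tables carry ERCC names. The reads were aligned to mouse build mm10 and quantified per gene and per transcript with GENCODE annotation M4, per the text files the submitters placed beside the tables. The names and versions of the aligner and quantifier, and whether counting used strand, are not given in the sources used here, so overlapping and antisense genes are uncertain.

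Each library had a table per gene and a table per transcript. The deposited expected counts are estimated reads per feature, which need not be whole because reads that match several features were shared out by the authors' quantifier. The deposited TPM values, transcript abundances adjusted for length, are scaled to the same fixed sum over all features of a library, spike-ins and short numbered features included. The deposited FPKM values, fragment counts scaled by length and library size, were used only as an alternative to TPM. The percent of each gene's transcripts held by each transcript is the authors' own column, per the file headers. The bounds of the quantifier's TPM interval were read and are not reported.

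The gene tables held 43346 mouse genes, 96 ERCC spike-ins, 1 phiX feature and 26248 features whose identifier is only a number, with a median length of 73 nt. Gene names, classes and coordinates came from GENCODE M21 on the same build, matched by identifier without its version, and 42462 genes (98.0%) matched. The list gene Ahsp was not matched and is not analysed here. No column of another sample was present in the tables used (0 columns).

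The total expected count was 36244861 in the replicate 1 library and 39415002 in the replicate 2 library. A count of 0 allows up to 3 counts at 95% confidence. Intervals and this floor cover counting error only, since reads without molecular identifiers are not independent molecules.

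The tests, the 35 gene lists, the 36 gene pairs, the rule for naming genes and the alternative settings were chosen before the data were examined. Named are the 20 nuclear protein-coding genes with the highest mean TPM, the 3 highest members of each list and any member below 1 TPM in both libraries, both genes of each pair, the 8 genes with the largest TPM ratio in each direction among those that differed, and 9 genes for transcripts (Wt1, Fgfr2, Ret, Pax2, Slc12a1, Cd44, Nphs1, Six2 and Igf2). Magi2, Star, Alb, Xist as a contrast to Eif2s3y, Klf1, Ckm, Myh11, the any-class genes Rn7s1, Rn7s2 and Gm28437, and the genes named in the closing section were chosen after their values were seen. The values of 4 genes that fall under this rule, and of 2 pairs, are not reported here.

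With 2 libraries in 1 group, no comparison between groups was possible, and no p was computed, since 2 libraries leave 1 degree of freedom. A gene was detected at 1 TPM or more in both libraries. Agreement was measured as Pearson's r and Spearman's rho of log2(TPM + 1) over genes at 1 TPM or more in either library. Replicate error was the median and 95th percentile of the absolute log2 TPM ratio over genes detected in both libraries. It was taken in bins of mean TPM with edges at 1, 3, 10, 30 and 100. The biological coefficient of variation is the square root of edgeR's common dispersion, fitted with an intercept only on expected counts rounded to whole numbers, after filterByExpr and with TMM factors. The chi-square used genes with at least 10 counts in total. Shifts of lists were set against 10000 random lists of the same size drawn from the same bins of mean TPM, over members at 1 TPM or more in both libraries. Pair differences used a pseudocount of 1, and a lower gene below 1 TPM was held to the limit of the lowest bin. Genes that differed needed a mean expected count of 100 and a TPM ratio of 2, and have exact Clopper-Pearson intervals of the count ratio at 95%. Wt1 and Fgfr2 forms were assigned by translating the M21 transcripts of the same identifiers. For Fgfr2, 10 of the 11 IIIb transcripts had the same length there as in the deposited table.

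The alternatives were other detection thresholds (0.5 and 5 TPM), a pseudocount of 0.1, no filter on low values, FPKM, TPM rescaled over nuclear genes, CPM (counts scaled to library size) with TMM factors, DESeq2's size factors and gene-wise dispersions, list means, all list members, a minimum of 20 counts, a 3-fold threshold, a chi-square minimum of 100 counts, and each library alone.

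For hypotheses in the closing section, 12 further marker lists were written after the list shifts were seen. Of these, 6 (adrenal, skeletal muscle, heart muscle, smooth muscle, urothelium and ureter, arterial endothelium) were written before the differing genes were seen, and 6 (bone, cartilage, limb patterning, intestinal epithelium, epidermis, exocrine pancreas) after that but before their own medians were. None shares a gene with the 35 lists.

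The chi-square, coefficient of variation, replicate error, differing genes, list shifts, pairs and shared transcripts were tested on simulated data, and the other steps were not. In counts drawn for the real genes with no more than sampling noise, the chi-square over its degrees of freedom came to 0.999, and a simulated coefficient of variation of 0.1 was recovered as 0.0981 over 17809 genes. For the count of differing genes, run on 13531 genes, 50 of 50 genes changed 3-fold were found, likewise 50 of 50 at 4-fold and 50 of 50 at 8-fold, against 1 of 50 at 1.5-fold and 3 of 13331 unchanged genes. For lists of 10 genes, 7% of 200 unchanged lists and 100% of 200 lists shifted by 0.5 fell outside the central 95%. For pairs, 500 of 500 pairs set 4-fold apart and 0 of 500 equal pairs were called, and for transcripts 800 of 800 unswitched genes of 1000 were called shared. The simulations were simpler than the data. Pairs had the same noise at every level and no gene below 1 TPM. Transcripts shared no reads. Genes were changed only well above the count minimum, on counts scaled to library size. Errors from low levels, transcript length and the division of reads were therefore not tested. The tools were Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, Biopython 1.88 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0.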

Results

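Total RNA was measured in the kidneys of mouse embryos at embryonic day 15.5, an age at which new nephrons are still forming at the edge of the organ. The only group, embryonic kidney, was represented by 2 biological replicate libraries, each from pooled kidneys of both sexes of the B6NCrl strain. The replicate 1 library came from 78 embryos and held 36244861 expected counts, and the replicate 2 library came from 62 embryos and held 39415002. The design holds no treatment and no other tissue. It allows 3 kinds of comparison: levels of genes and cell type lists within the tissue, differences between chosen pairs of genes, and differences between the replicate pools. Levels are TPM, a length-adjusted relative abundance, as mean ± SD over the 2 libraries (n = 2), unless values are given per library. Coordinates are on mouse build mm10.

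Nephron progenitor genes were expressed at clear levels in both libraries. All 10 genes of the progenitor list reached 1 TPM in both, with a list median of 28.9 ± 2.22 TPM. Cited1, a transcriptional co-regulator of uninduced progenitors (ENSMUSG00000051159.12; chromosome X, 102247381 to 102252181), was the most abundant at 126 ± 2.33 TPM. Crym, which encodes a thyroid hormone-binding crystallin, followed at 60.6 ± 1.58 TPM, and Eya1, a co-activator needed for kidney formation, was at 41.3 ± 3.96 TPM. Six2, the transcription factor that keeps progenitors undifferentiated (ENSMUSG00000024134.11; chromosome 17, 85684277 to 85688274), stood at 14.6 ± 0.997 TPM. All 12 genes of early nephron structures were also detected, with a median of 23.9 ± 0.513 TPM. Among them the transcription factors Pax8 and Osr2 reached 104 ± 0.361 and 77 ± 0.0566 TPM, and the Notch ligand Jag1 reached 43.6 ± 1.75 TPM.

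Genes of each differentiated nephron segment were detected, with the podocyte and proximal lists above the distal list. The 12 podocyte genes had a median of 21.7 ± 0.704 TPM. Tcf21 and Wt1, transcription factors that are also active outside podocytes, led at 265 ± 5.501 and 104 ± 1.59 TPM, and the surface sialomucin Podxl stood at 51.9 ± 1.39 TPM. The 12 proximal tubule genes had a median of 17.4 ± 1.05 TPM, led by the sodium-phosphate cotransporter Slc34a1 at 101 ± 7.07, the creatine-pathway enzyme Gatm at 38.3 ± 3.46 and the gluconeogenic enzyme Fbp1 at 37.4 ± 4.01 TPM. The 7 loop of Henle genes had a median of 7.495 ± 0.502 TPM, with the sodium-potassium-chloride cotransporter Slc12a1 at 32.3 ± 2.17, the claudin Cldn10 at 19.5 ± 1.598 and Cldn19 at 10.8 ± 0.0919 TPM. The 6 distal tubule genes had the lowest median of the nephron lists, 1.55 ± 0.269 TPM. Wnk1, a kinase made in many cell types, accounted for the highest value there at 33.3 ± 0.721 TPM, while the thiazide-sensitive cotransporter Slc12a3 was at 2.42 ± 0.0849 and Klhl3 at 1.77 ± 0.382 TPM. The magnesium channel Trpm6 (0.3 and 0.44 TPM in the replicate 1 and 2 libraries) and the calcium-binding protein gene Pvalb (0 and 0.09 TPM) stayed below 1 TPM in both.

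Tip and collecting duct genes of the ureteric tree were expressed at levels close to those of the progenitors, and intercalated cell and urothelium genes at lower ones. The 9 genes of ureteric tips had a median of 29.5 ± 0.276 TPM, led by the GDNF co-receptor Gfra1 at 53.3 ± 1.82 and the ETS transcription factors Etv4 and Etv5 at 48.6 ± 0.841 and 48.5 ± 0.0424 TPM. The 16 collecting duct genes had a median of 25.9 ± 1.4 TPM, led by the keratins Krt8 and Krt18 at 191 ± 4.16 and 149 ± 3.42 TPM and by the calcium-binding protein gene Calb1 at 133 ± 17 TPM. The 6 genes of intercalated cells, which move acid and base, had a median of 4.67 ± 0.721 TPM. Slc4a1, an anion exchanger that red cells also make, stood at 13.4 ± 4.16, the transcription factor Foxi1 at 10.9 ± 0.318 and the proton pump subunit Atp6v0d2 at 4.96 ± 2.17 TPM. The anion exchanger Slc26a4 stayed below 1 TPM in both libraries, at 0.63 and 0.8. The 8 urothelium genes had a median of 2.66 ± 0.9899 TPM, with the uroplakins Upk3a, Upk1b and Upk1a at 21.1 ± 0.9899, 6.34 ± 3.12 and 3.94 ± 1.03 TPM, and the signal protein gene Shh below 1 TPM at 0.65 and 0.87.

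Stroma, vessels and blood gave some of the highest levels. The 15 interstitial stroma genes had a median of 73.3 ± 4.41 TPM, led by the fibrillar collagens Col1a1 and Col3a1 at 905 ± 4.04 and 867 ± 199 TPM and by the enkephalin precursor Penk at 292 ± 6.74 TPM. The 9 genes of mesangium, pericytes and smooth muscle had a median of 40.6 ± 3.83 TPM, with smooth muscle actin Acta2 at 302 ± 153, renin (Ren1) at 237 ± 45.03 and Tagln at 53.1 ± 21.5 TPM. The 10 endothelial genes had a median of 36.8 ± 2.43 TPM, led by Plvap of endothelial diaphragms at 112 ± 3.51, the sialomucin Emcn at 70.2 ± 0.0283 and the TGF-beta co-receptor Eng at 62.7 ± 5.402 TPM. The 10 macrophage and leukocyte genes had a median of 7.82 ± 1.08 TPM, led by lysozyme Lyz2 at 62.98 ± 3.95 and the complement genes C1qb and C1qa at 37.1 ± 3.03 and 17.96 ± 2.397 TPM. The 11 matched erythroid genes had a median of 63.98 ± 8.74 TPM, and the adult globins Hba-a2, Hbb-bs and Hba-a1 stood at 10397 ± 1134, 5169.8 ± 233 and 3867 ± 525 TPM. Levels of single adult globin genes are uncertain because near-identical copies share reads.

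Markers of neighbouring organs were also measured, and several differed between the pools. The nerve and Schwann cell list had a median of 5.19 ± 2.21 TPM, led by the neurotrophin receptor Ngfr at 22.2 ± 1.48, the neuronal protein gene Stmn2 at 19.4 ± 10.6 and the neuronal RNA-binding protein gene Elavl4 at 12.4 ± 0.552 TPM. In that list Sox10 (0.33 and 0.78 TPM) and Foxd3 (0.13 and 0.14) stayed below 1 TPM in both libraries. The steroid-producing enzymes Cyp11a1, Cyp21a1 and Hsd3b1 led the adrenal cortex list at 25.4 ± 17.6, 22.9 ± 19.6 and 20.4 ± 14.6 TPM, against a list median of 13.2 ± 10.4, and Cyp17a1 stayed below 1 TPM at 0.1 and 0.64. The adrenal medulla list had a median of 11.5 ± 11.7 TPM, led by tyrosine hydroxylase Th at 16.6 ± 17.1 and the granins Chga and Chgb at 14.5 ± 13.6 and 14.3 ± 15.2 TPM. Skeletal muscle genes had a median of 19.5 ± 10.1 TPM, led by the actins Acta1 and Actc1 at 149 ± 58.95 and 103 ± 29.7 and the troponin Tnnt3 at 28.5 ± 13.4 TPM. Liver genes had a median of 25.8 ± 11.3 TPM, led by alpha-fetoprotein (Afp) at 129 ± 49.2, transferrin (Trf) at 94.9 ± 54.3 and Apoa1 at 40.7 ± 19.7 TPM. The gonad and germ cell list had a median of 0.315 ± 0.1202 TPM, with Inha at 7 ± 2.93, Dhh at 1.52 ± 0.0707 and Insl3 at 1.205 ± 0.233 TPM. Its other members Gata4 (0.55 and 0.57 TPM), Ddx4 (0.23 and 0.4), Pou5f1 (0.1 and 0.04), Dazl (0.07 and 0.07) and Amh (0.08 and 0.05) were below 1 TPM in both, and Sry had 0 counts in both, which allows up to 3 counts in each.

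Dividing cells and growth programs were prominent. The 12 proliferation genes had a median of 164 ± 1.33 TPM, led by the mitotic kinase Cdk1 at 399 ± 6.15, survivin (Birc5) at 261 ± 13.2 and the replication clamp Pcna at 222 ± 13.8 TPM. Imprinted growth genes had a median of 280.5 ± 45.3 TPM, with Mest at 1745 ± 46.1, the growth factor Igf2 at 561 ± 3.04 and the cyclin-dependent kinase inhibitor Cdkn1c at 516 ± 41.4 TPM. Of 12 posterior Hox genes, which set position along the body, 10 were detected, led by Hoxa10, Hoxb7 and Hoxa9 at 134 ± 10.1, 49.4 ± 2.83 and 48.7 ± 7.16 TPM. The most posterior members Hoxa13 (0.11 and 0.35 TPM) and Hoxd13 (0.19 and 0.76) stayed below 1 TPM in both. Basement membrane genes had a median of 39.3 ± 3.68 TPM, led by the collagen Col4a1 at 227 ± 11.3, the laminin Lamb1 at 121 ± 4.49 and the collagen Col4a2 at 90.98 ± 4.04 TPM. All 18 genes mutated in inherited kidney disease were detected, with a median of 15.8 ± 1.19 TPM. The highest of these were Wt1 and then the transcription factor Gata3 at 84.1 ± 6.095 TPM.

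Metabolic genes were among the most abundant lists. The 12 glycolysis genes had a median of 426 ± 14.4 TPM, with Gapdh, Eno1 and Ldha at 1725 ± 8.92, 1563 ± 34.3 and 1308 ± 3.78 TPM. The 10 fatty acid oxidation genes had a median of 52.1 ± 2.19 TPM, with both subunits of the trifunctional protein, Hadhb and Hadha, at 128 ± 0.757 and 118 ± 1.93 and the dehydrogenase Acadl at 100.2 ± 1.18 TPM. The 13 mitochondrially encoded protein genes had a median of 1303 ± 122 TPM, led by mt-Atp6, mt-Atp8 and mt-Cytb at 7250.5 ± 579, 5475 ± 789 and 3027 ± 176 TPM. Values of single mitochondrial genes are uncertain, because Gm28437, a nuclear copy of mitochondrial sequence, was itself assigned 8008 ± 991 TPM. Which of these genes shares its reads was not worked out.

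Stress response, histone, non-coding and sex-linked genes covered a wide range. Immediate early genes had a median of 7.68 ± 0.0778 TPM, with Ier2 at 62.6 ± 3.46, Jun at 55.4 ± 1.92 and Dusp1 at 19.6 ± 1.15 TPM, and Fosb stayed below 1 TPM at 0.07 and 0.15. The heat shock list had a median of 53.7 ± 2.998 TPM, led by the constitutive chaperone Hspa8 at 2353 ± 84.6, the co-chaperone Dnajb1 at 64.7 ± 0.488 and Hspb1 at 58.8 ± 2.38 TPM. The inducible Hspa1b, which shares reads with its copy Hspa1a, was at 0.4 and 0.43 TPM. The hypoxia list had a median of 19.98 ± 0.856 TPM, led by Bnip3 at 85.5 ± 0.2404, the glucose transporter Slc2a1 at 73.5 ± 8.004 and the kinase Pdk1 at 35.7 ± 0.431 TPM. Histone genes with near-identical copies had a median of 20.8 ± 2.44 TPM, with Hist1h4d at 380 ± 41.5, Hist1h2ae at 171 ± 41.1 and Hist1h2bc at 104 ± 5.303 TPM, all uncertain for that reason. Among the non-coding RNAs, with a median of 61.6 ± 6.45 TPM, Malat1 reached 5674 ± 321, the transcription regulator Rn7sk 279 ± 26.8 and the RNase P RNA Rpph1 107 ± 13.1 TPM, and the telomerase RNA Terc stayed below 1 TPM at 0.63 and 0.35. In the sex-linked list, with a median of 18.5 ± 2.86 TPM, the Y-linked Eif2s3y and Ddx3y stood at 29.3 ± 3.24 and 22.4 ± 2.63 TPM and Xist, expressed from the inactive X chromosome, at 18.9 ± 3.42 TPM.

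In all, 34 of the 35 lists had a median of 1 TPM or more in both libraries, the exception being gonad and germ cells. Over single genes, 15108 reached 1 TPM in both libraries, of which 13387 were protein-coding, 774 long non-coding and 549 pseudogenes. No test applies to these levels, because there is 1 group, and a list's level also depends on which of its members other cell types make.

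**Figure D1:**
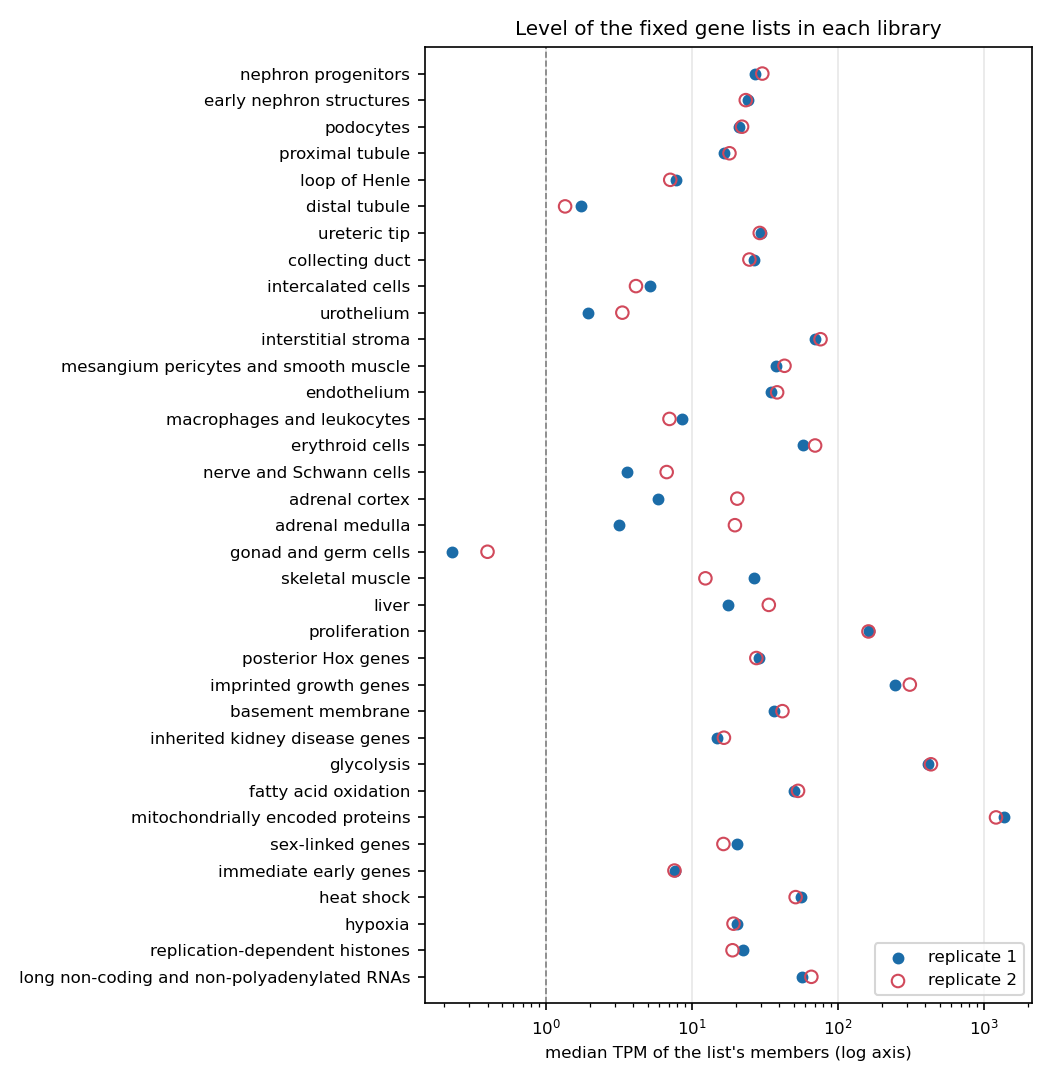
Median TPM of each of the 35 fixed gene lists (log axis) in the replicate 1 and replicate 2 libraries, with 1 point per library. The mitochondrially encoded genes lie highest, with a mean of 1303 TPM, and the gonad and germ cell list lies lowest, at 0.23 and 0.4 TPM.

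The most abundant nuclear protein-coding genes fell into a few groups. Red cell globins filled 4 of the 20 highest places, with Hbb-bt at 3705 ± 212 TPM after Hba-a2, Hbb-bs and Hba-a1. Cytoskeleton genes filled 3, namely Actb at 4970.2 ± 97.9, Tmsb4x at 2262 ± 62.8 and Actg1 at 1996 ± 71.4 TPM. The translation factor Eef1a1 stood at 4048 ± 154 TPM and the ribosomal protein genes Rpl41, Rps19 and Rpl32 at 3535 ± 164, 2139 ± 269 and 1924 ± 164 TPM. Chromatin was represented by Hist1h2ap at 3341 ± 38.5, Ptma at 2521 ± 208, Hmgn2 at 2219 ± 86.5 and H3f3a at 2179 ± 55.2 TPM. The remaining places were held by the cyclophilin Ppia at 4814 ± 434, ferritin light chain Ftl1 at 3755 ± 73.2, ubiquitin Ubb at 2608 ± 8.29, the chaperone Hspa8, and the ATP synthase subunit Atp5b at 2349 ± 22.2 TPM. Genes of any class were topped by Rn7s1 and Rn7s2, the RNA of the signal recognition particle, at 13972 ± 337 and 13972 ± 338 TPM. These 2 near-identical copies share reads, so only their sum is certain. The 10 most abundant genes of any class took 7.97 ± 0.0527% of the TPM total, globin genes 2.34 ± 0.217%, the mitochondrial chromosome 3.15 ± 0.335% and the added spike-in RNAs 6.56 ± 1.10%. As shares of counts these were lower, at 2.53%, 0.782%, 1.67% and 2.96%. The mitochondrial share leaves out the nuclear copy Gm28437, at 145872 and 131807 counts in the replicate 1 and 2 libraries, against 655868 and 606381 for that chromosome. Globin, ribosomal protein, actin and histone genes all have near-identical copies, so each single value here is less certain than the group.

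Of 36 chosen gene pairs, 30 differed by more than replicate error in both libraries. Values are log2(TPM + 1) of the first gene minus that of the second, as mean ± SD (n = 2). The tissue held more Cited1 than Six2 transcript, with Six2/Cited1 at -3.02 ± 0.119. Six2 in turn exceeded Foxd1, the transcription factor of stromal progenitors, at 0.89 ± 0.0584, and the slit diaphragm gene Nphs1 at 1.82 ± 0.2004. Nphs1, which encodes nephrin (ENSMUSG00000006649.12; chromosome 7, 30458315 to 30487223), stood at 3.46 ± 0.898 TPM. Wt1 exceeded Pax2, a nephron and ureteric transcription factor, by 1.80 ± 0.0306, with Pax2 at 29.2 ± 1.096 TPM. In the tubule, the endocytic receptor Lrp2 lay below Slc34a1 at -2.98 ± 0.0796 and above its partner Cubn at 1.42 ± 0.102. Slc12a1 exceeded Umod, the uromodulin gene of the same segment, by 2.98 ± 0.161.

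Collagen IV, globin and Hox genes showed wide gaps within a gene family. Col4a1 exceeded Col4a3 by 6.17 ± 0.033 and Col4a2 exceeded Col4a4 by 4.56 ± 0.165, where the second of each pair belongs to the mature glomerular basement membrane and stood at 2.18 ± 0.0849 and 2.905 ± 0.276 TPM. Among laminins, Lama1 lay below Lama5 at -0.80 ± 0.08403 and Lamb1 above Lamb2 at 1.48 ± 0.0836. Adult globins exceeded their embryonic forms, Hba-a1 over Hba-x by 6.55 ± 0.364 and Hbb-bt over Hbb-y by 4.38 ± 0.302. Igf2 exceeded Igf1 by 4.24 ± 0.0849 and the neighbouring imprinted RNA H19 by 0.61 ± 0.0972. Hoxa11 and Hoxd11, which act in kidney formation, exceeded Hoxa13 and Hoxd13 by 4.58 ± 0.191 and 3.92 ± 0.366. Fuel genes differed as well, with Slc2a1 over Slc2a2 at 2.55 ± 0.277, Hk1 over Hk2 at 1.45 ± 0.158 and Ldha over Ldhb at 1.27 ± 0.0329.

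Signalling and growth pairs differed as well. Kdr, the main VEGF receptor, exceeded its ligand Vegfa, with Vegfa/Kdr at -2.44 ± 0.00211. Afp exceeded albumin by 1.76 ± 0.186. Wnt11 of the ureteric tip exceeded Wnt7b of the stalk by 1.11 ± 0.0558, Ccnd1 exceeded Ccnd2 by 0.75 ± 0.104, and the mesenchymal cadherin Cdh2 lay below the epithelial Cdh1 at -0.91 ± 0.0359. Igf2bp1/Igf2bp2, Notch1/Notch2 and Mycn/Myc also differed, at -0.84 ± 0.0186, -0.47 ± 0.0933 and -0.46 ± 0.0832. For 6 pairs the difference did not exceed replicate error in both libraries. These were Gdnf/Ret at -0.33 ± 0.00657, Slc5a1/Slc5a2 at 0.64 ± 0.328, Aqp2/Aqp1 at 0.63 ± 0.6903, Pkd1/Pkhd1 at 0.50 ± 0.0405, Fgfr1/Fgfr2 at -0.27 ± 0.00531 and Bmp4/Bmp7 at -0.39 ± 0.105. A pair was called where both libraries gave the same sign and both differences exceeded the 95th percentile of the absolute log2 ratio between libraries at the abundance of the lower gene. The smallest exact 2-sided p from 2 paired libraries is 0.5, so none is given. On CPM, counts scaled to library size, which take no account of transcript length, Lama1/Lama5, Igf2bp1/Igf2bp2 and Ccnd1/Ccnd2 turned direction and the calls for Igf2/H19, Mycn/Myc and Wnt11/Wnt7b ended, while that for Six2/Foxd1 ended when TPM was rescaled over nuclear genes. Calls were gained on CPM for Gdnf/Ret (-1.34), Slc5a1/Slc5a2 (1.94), Pkd1/Pkhd1 (2.15) and Bmp4/Bmp7 (-1.20), on rescaled TPM for Bmp4/Bmp7 and on FPKM for Fgfr1/Fgfr2. Other called differences that moved 1.5 times or more on CPM were Six2/Cited1 (to -1.74), Lrp2/Slc34a1 (-1.03), Igf2/Igf1 (2.30), Notch1/Notch2 (-0.80) and Vegfa/Kdr (-3.66).

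**Figure D2:**
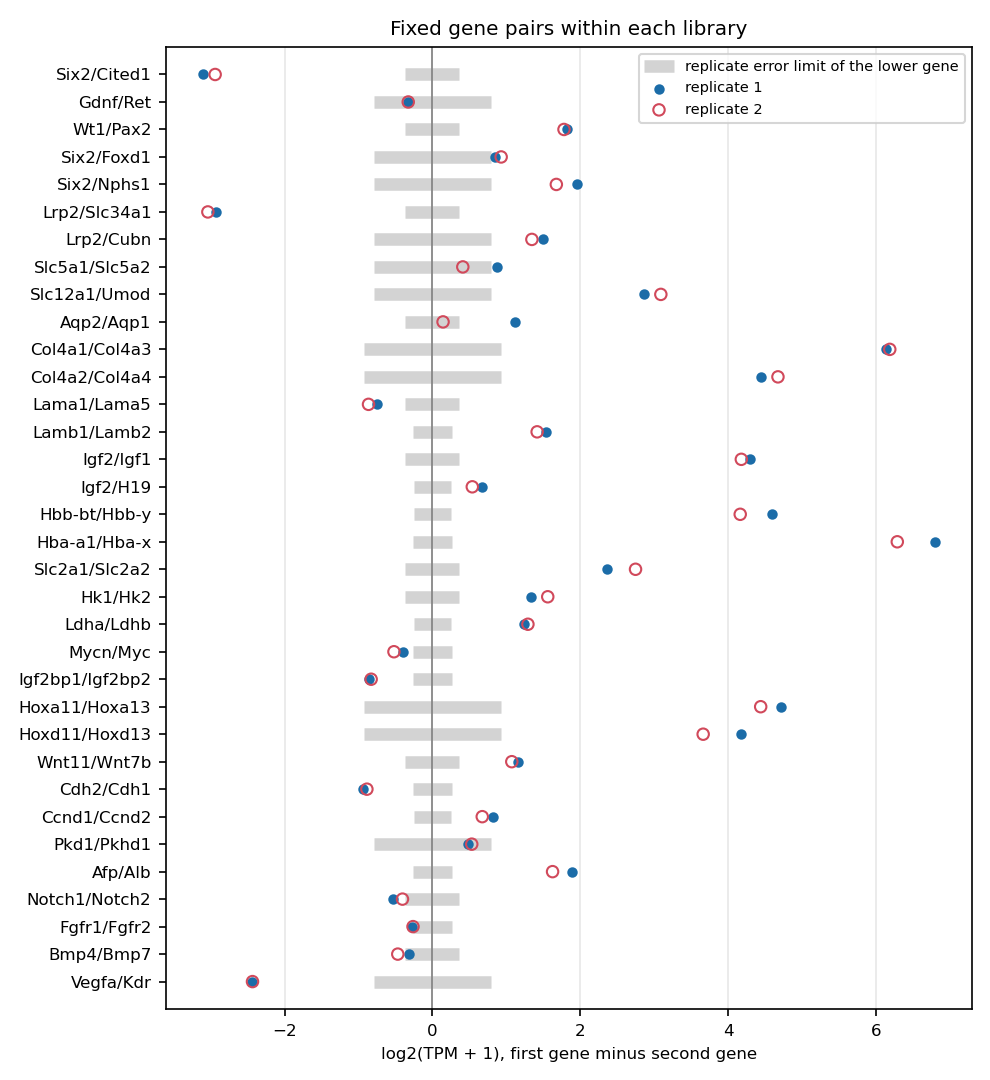
Difference of log2(TPM + 1) between the genes of 34 of the 36 pairs (first minus second), with 1 point per library and a line at 0. The points of the 2 libraries lie close together for most pairs, and the widest separation between libraries is that of Aqp2/Aqp1, at 1.12 and 0.14.

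Genes of other tissues differed most between the replicate pools, and shifts of kidney epithelial lists were smaller. The adrenal medulla list was higher in the replicate 2 library, with a median log2 ratio of 2.44 and all 5 detected members higher there, and so was the adrenal cortex list, at 1.60 with 7 of 7. The nerve and Schwann cell list (1.11, 6 of 7 members), the liver list (0.86, 7 of 7) and the urothelium list (0.54, 4 of 5) were also higher in replicate 2. The skeletal muscle list was higher in the replicate 1 library, at -0.67 with 8 of 8 members. Smaller shifts toward replicate 2 were found for mesangium, pericytes and smooth muscle (0.29, 8 of 9), erythroid cells (0.28, 10 of 11), imprinted growth genes (0.15, 9 of 10), fatty acid oxidation (0.12, 9 of 10), interstitial stroma (0.12, 13 of 15) and endothelium (0.12, 10 of 10). The sex-linked list shifted the same way (0.23, 3 of 5), but Xist, at 21.4 and 16.5 TPM, went against the Y-linked Eif2s3y, at 27.03 and 31.6. Shifts toward replicate 1 were found for mitochondrially encoded genes (-0.18, 13 of 13), the loop of Henle (-0.14, 5 of 7), the collecting duct (-0.12, 14 of 16), posterior Hox genes (-0.11, 7 of 10) and histones (-0.10, 6 of 10). Nephron progenitors (-0.00), podocytes (0.04) and ureteric tips (-0.07) did not stand apart.

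A list stood apart where its median log2 ratio lay outside the central 95% of 10000 random lists of the same size and abundance. This held for 18 of 35 lists, where lists of unrelated genes would give about 1.75, and describes these 2 pools only. The random lists hold genes drawn independently, whereas members of a list can vary together. The number to be had by chance may therefore be larger, above all for the small shifts. With the mean of members instead of the median, 13 lists stood apart, and the calls lost were those for the loop of Henle, endothelium, fatty acid oxidation, sex-linked genes and histones, while mesangium, pericytes and smooth muscle (0.55), imprinted growth genes (0.22) and the collecting duct (-0.19) shifted more. Over all members on log2(TPM + 1) the same 18 stood apart, with smaller shifts for the nerve and Schwann cell list (0.38) and the urothelium list (0.31). On CPM the call for fatty acid oxidation was lost, and early nephron structures (-0.10), proximal tubule (0.10), intercalated cells (0.26) and basement membrane (0.08) gained one. With TPM rescaled over nuclear genes the call for the loop of Henle was lost, and mitochondrial genes are not on that scale.

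**Figure D3:**
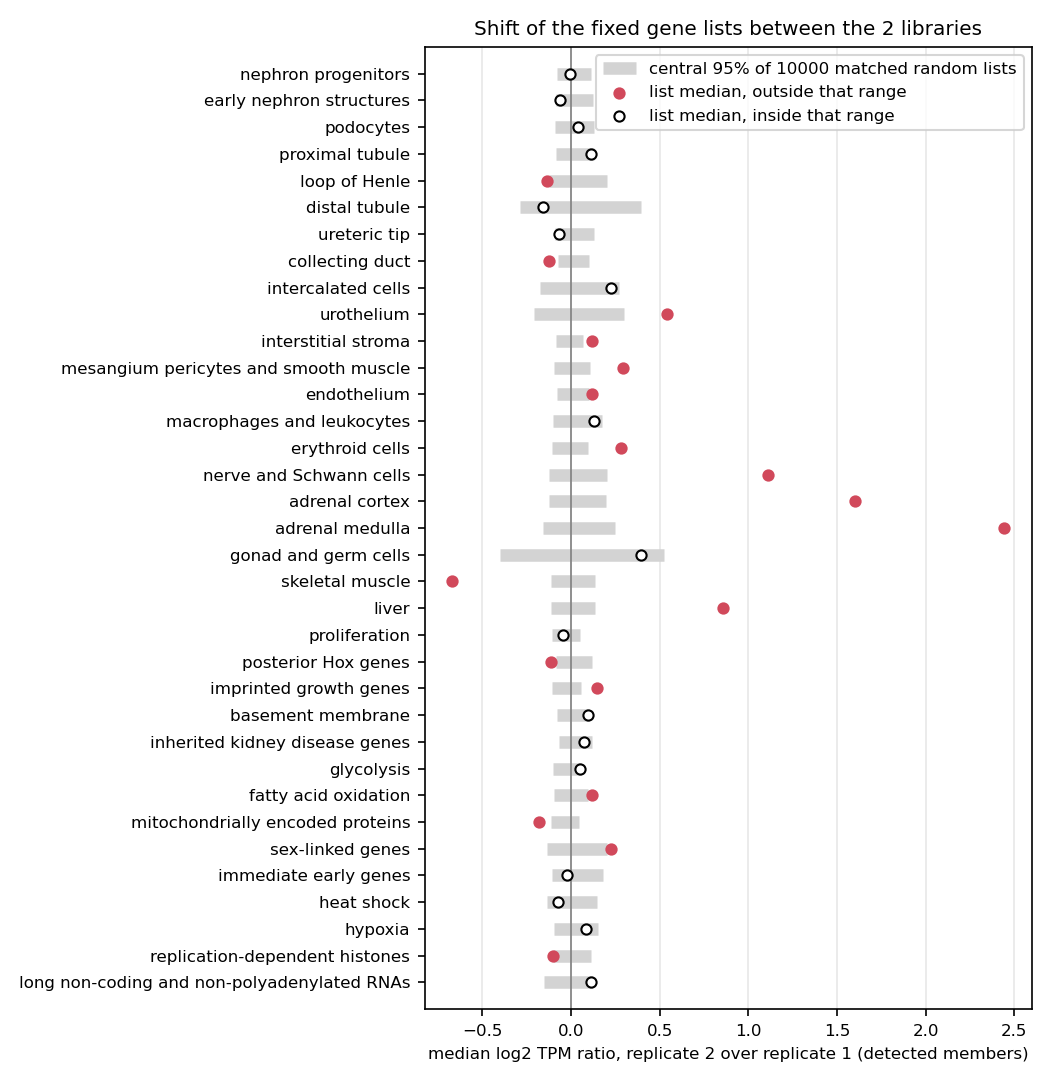
Median log2 TPM ratio, replicate 2 over replicate 1, of each fixed list (points), with the central 95% of 10000 matched random lists (grey bars) and a line at 0. The adrenal lists lie farthest to the right, at 2.44 and 1.60, and the skeletal muscle list farthest to the left, at -0.67.

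Across genes the pools were otherwise close. Genes at 100 TPM or more, such as Actb at 5039 and 4901 TPM and Gapdh at 1732 and 1719 TPM, had a median absolute log2 ratio of 0.08, and 95% of them lay within 0.25. Among genes detected in both libraries, those averaging 1 to 3 TPM, such as Magi2 at 2.48 and 2.15 TPM, had a median of 0.24. Of these, 95% lay within 0.92. Genes at 1 TPM or more in only 1 library, 463 in replicate 1 and 586 in replicate 2, are left out, so the spread at low levels may be understated. Over 16157 genes Pearson's r of log2(TPM + 1) was 0.985 and Spearman's rho 0.986, across genes, which are not independent replicates. The biological coefficient of variation was 0.106 by edgeR's common dispersion. By DESeq2's median gene-wise dispersion, which rests on 1 degree of freedom per gene, it came to 0.00213, too low for the chi-square given below. Of genes detected in both libraries, 98.2% lay within 2-fold. The chi-square of the counts over its degrees of freedom was 11.3 over 19857 genes, where counting noise alone gives about 1. Counts simulated with a coefficient of variation of 0.1 gave 18.99. The spike-in RNAs were higher in the replicate 2 library by a median log2 ratio of 0.36 (56 spike-ins), with a median absolute deviation of 0.0647. Whether both libraries received equal amounts of them was not measured here.

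A small share of single genes differed widely between the pools. Of 13507 genes with a mean expected count of 100 or more, 166 (1.23%) differed 2-fold or more in TPM, 54 higher in replicate 1 and 112 higher in replicate 2. Ibsp, which encodes bone sialoprotein (ENSMUSG00000029306.8; chromosome 5, 104299171 to 104311469), stood at 131 and 0.12 TPM in the replicate 1 and 2 libraries, 1096-fold (95% interval 524 to 3109) higher in replicate 1. The collagenase Mmp13, made by cartilage and bone cells (chromosome 9, 7272514 to 7283331), stood at 45.9 and 0.15 TPM, 306-fold (95% interval 169.7 to 652) higher in replicate 1, and the bone matrix gene Dmp1 (chromosome 5, 104202613 to 104214102) at 12.8 and 0.06 TPM, 213-fold (95% interval 87.6 to 828) higher. Panx3, a channel gene of bone and cartilage (chromosome 9, 37659902 to 37669235), had 239 and 0 expected counts in the replicate 1 and 2 libraries, with a lower 95% limit of the count ratio of 69.4. Mmp9, a gelatinase abundant in osteoclasts, stood at 34.2 and 2.12 TPM, 16.1-fold (95% interval 13.3 to 18.5) higher. Also higher in replicate 1 were 3 genes known from goblet cells, the trefoil factor Tff3 at 40.7 and 1.15 TPM (35.4-fold (95% interval 20.01 to 69)), the disulfide isomerase Agr2 at 26.1 and 1.09 TPM (23.9-fold (95% interval 15.1 to 39.1)) and Clca1 at 6.22 and 0.48 TPM (12.96-fold (95% interval 9.21 to 18.7)).

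In the other direction, the 8 genes with the largest ratios included 3 known from the adrenal medulla. The granin Chgb (ENSMUSG00000027350.8; chromosome 2, 132781278 to 132795079) stood at 3.56 and 25.1 TPM, 7.05-fold (95% interval 6.13 to 8.11) higher in replicate 2. Th (chromosome 7, 142892752 to 142931128) stood at 4.48 and 28.7 TPM, 6.41-fold (95% interval 5.42 to 7.398) higher, and Dbh, which makes noradrenaline (chromosome 2, 27165233 to 27183200), at 2.85 and 15.5 TPM, 5.44-fold (95% interval 4.62 to 6.43) higher. The pancreatic lipase-related gene Pnliprp1 stood at 0.43 and 5.46 TPM, 12.7-fold (95% interval 7.63 to 22.6) higher, and the keratin Krt6a at 0.51 and 3.08 TPM, 6.04-fold (95% interval 3.99 to 9.37) higher. A gene with no name in the annotation used, ENSMUSG00000103057.1, stood at 2.64 and 64.1 TPM, 24.3-fold (95% interval 19.2 to 31.4) higher. Gm13304 had 0 and 209.9 expected counts and Gm14440 0 and 382. Both belong to families of near-identical genes, so reads assigned to them are uncertain and no fold is given.

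By list, 6 of 8 adrenal cortex genes, 4 of 6 adrenal medulla genes, 4 of 10 nerve genes and 4 of 8 liver genes differed 2-fold or more, all higher in replicate 2. Examples are Star, the cholesterol carrier of steroid-making cells, at 4.71 and 16.4 TPM and albumin (Alb) at 24.7 and 52.4 TPM. Acta2 (193 and 410.1 TPM) and the smooth muscle myosin Myh11 (5.54 and 24.05 TPM) differed the same way, as did Upk1b (4.13 and 8.54) and the red cell factor Klf1 (2.79 and 5.81). Ckm, muscle creatine kinase (37.01 and 14.3 TPM), was the 1 gene of the fixed skeletal muscle list that differed, and was higher in replicate 1. Of the 90 genes in the 9 kidney epithelial lists 85 had a mean count of 100 or more, and 0 of these differed 2-fold or more, where the overall rate gives about 1.04. The largest ratio among them was that of Atp6v0d2, at 6.49 and 3.42 TPM. These counts compare 2 libraries, no p was computed, and the intervals are exact Clopper-Pearson intervals of the count ratio that cover counting error only. For 16 of the 166 genes the TPM ratio lay outside this interval, and for 3 of them the interval included 1, so part of these differences lies in transcript lengths or assignment and not in counts. With a mean count of 20 as the minimum, 578 genes differed, and at 3-fold 59 did.

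**Figure D4:**
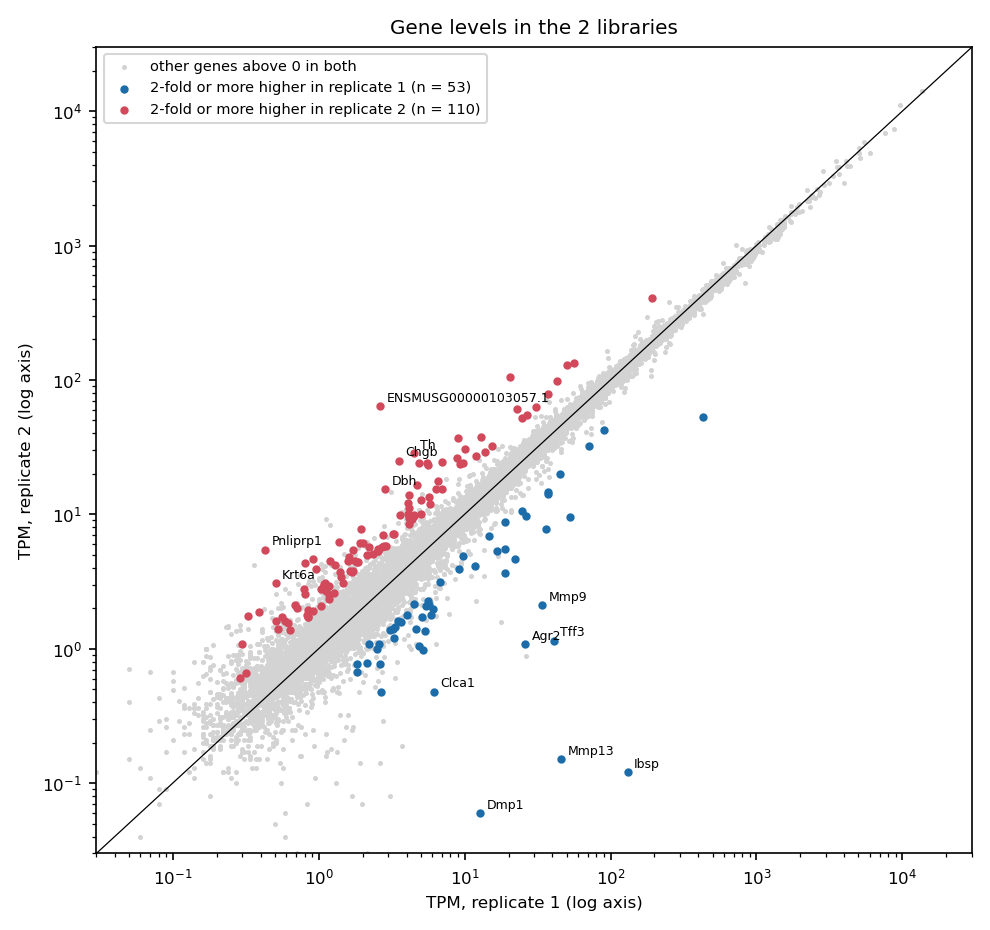
TPM of each gene in the replicate 1 library against the replicate 2 library, both on log axes, with genes that differed 2-fold or more in colour and a line of equal values. Genes at 0 in either library are not drawn, so 53 of the 54 genes higher in replicate 1 and 110 of the 112 higher in replicate 2 appear. Ibsp, Mmp13 and Dmp1 lie farthest from the line.

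Transcript use was alike in the pools for most genes, and the Wt1 and Fgfr2 genes show what the transcript values can resolve. Wt1 transcripts whose protein holds the KTS insert between zinc fingers made up 69.2 ± 0.0547% of Wt1 TPM, and those without it 20.3 ± 0.762%, with 10.5 ± 0.708% in transcripts that reach neither form (SD, n = 2). Fgfr2 transcripts with the IIIb exon, the form of epithelia, made up 20.8 ± 1.33% and those with the IIIc exon, the form of mesenchyme, 25.7 ± 0.345%, while 53.5 ± 0.990% could not be assigned to either. Ret, the GDNF receptor, was mostly the longer Ret-202 (75.4 ± 2.47%), and Pax2 was spread over Pax2-203 (46.3 ± 1.84%), Pax2-201 (31.4 ± 0.912%) and Pax2-202 (22.3 ± 0.926%). Slc12a1-201 held 50.7 ± 6.05% of Slc12a1. Six2 came from 1 of its 2 transcripts. The Cd44 forms Cd44-207 (50.6 ± 11.1%) and Cd44-203 (42.4 ± 10.1%) changed places between libraries, as did Nphs1-205, a 752 nt transcript annotated for nonsense-mediated decay (44.2 ± 5.96%), and the full-length Nphs1-201 (36.9 ± 11.6%), and Igf2-203 (40.4 ± 4.19%) and Igf2-208 (34.6 ± 4.74%). In all, 9349 of 10206 genes with 2 or more transcripts (91.6%) had the same most abundant transcript in both libraries, which held a median of 70.0% of the gene's TPM in replicate 1 and 69.4% in replicate 2. Of the 857 others, 214 had more than 50% in a different transcript in each library. Shares rest on the quantifier's division of reads among overlapping transcripts, and no test was run on them.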

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

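No test was chosen after a result was seen in this part. The features whose identifier is only a number were used in no comparison. They held 64 expected counts in the replicate 1 library and 66.4 in the replicate 2 library, which is above the 3 counts that a count of 0 allows. Of the 26248 features, 9 had counts in replicate 1 and 8 in replicate 2. The largest, 255 nt long, held 44 counts in replicate 1 and 54 in replicate 2. As CPM of each library, the sums were 1.77 and 1.68.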

How the results depend on the processing

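No setting here was added after a result was seen. No paired analysis was possible because there is 1 group. Of the alternatives, Pearson's r was 0.958 with a pseudocount of 0.1, 0.994 without a filter, 0.991 on CPM, 0.987 on FPKM and 0.984 on TPM rescaled over nuclear genes, and Spearman's rho was 0.957 without a filter, 0.993 on CPM and 0.987 on FPKM. The median absolute log2 ratio was 0.092 at 5 TPM, 0.10 on CPM and 0.11 on rescaled TPM, and its 95th percentile 0.34 at 5 TPM and 0.52 on CPM; raising the threshold removes low genes by construction. The coefficient of variation was 0.125 without a filter and 0.00213 by DESeq2's median gene-wise dispersion. The latter rests on 1 degree of freedom per gene and is too low for the chi-square ratio. The chi-square ratio was 14.2 at 100 counts or more. Genes that differed numbered 578 at a mean count of 20 and 59 at 3-fold. As shares of counts instead of TPM, spike-ins took 2.96%, the mitochondrial chromosome 1.67%, globins 0.782% and the 10 most abundant genes 2.53%, since TPM weights short genes up. On CPM Lama1/Lama5 was 0.67, Igf2bp1/Igf2bp2 0.23 and Ccnd1/Ccnd2 -0.71; that scale ignores transcript length, so differences between genes move with it.

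The other counts stayed within 1.5 times of their value. Genes detected ranged from 15571 to 15694 in 1 library alone, and were 16706 at 0.5 TPM, 11238 at 5 TPM, 14152 on FPKM and 15304 on rescaled TPM. Lists at 1 TPM or more numbered 34 in either library alone, 29 at 5 TPM, 33 on FPKM, where the distal tubule list averaged 1.04, and 33 on rescaled TPM, which leaves out mitochondrial genes. Lists that stood apart numbered 21 on CPM, of which 17 were among the 18, 16 on rescaled TPM (16 among the 18), 13 by means (13) and 18 with all members (18). Genes that differed numbered 156 on CPM (145 among the 166) and 167 on rescaled TPM (165). Pairs called ranged from 31 to 33 with 1 library alone, where Bmp4/Bmp7 was called without replicate 1 (-0.47) and Slc5a1/Slc5a2 (0.88), Aqp2/Aqp1 (1.12) and Fgfr1/Fgfr2 (-0.27) without replicate 2. The shared most abundant transcripts numbered 7669 of 8173 at 5 TPM and 9580 of 10206 by counts. The median log2 ratio of all genes was 0.018 on deposited TPM, 0.0026 on FPKM, 0.036 on rescaled TPM and -0.0010 on CPM. Genes averaging 1 to 3 TPM had the widest spread of the bins, with 95% of absolute log2 ratios within 0.92. How much of this came from depth was not measured.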

Other observations

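All marker lists in this part were written after the shifts of the first lists were seen, and the adrenal scaling test, the widening of the muscle pattern to bone and the rule that the limb value must exceed its members' spread were chosen only after the results were seen. Heart muscle and scaling were at first set against the muscle pattern and were left out of the weighing after their values were seen. The heart list held 1.74 and 2.48 TPM in the replicate 1 and 2 libraries, a median log2 ratio of 0.10, at the 70.2 percentile of matched random lists.

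Marker genes of further tissues were also compared. In the intestinal list 11 of 12 genes were higher in the replicate 1 library, with a median difference of log2(TPM + 1) of -0.53 against a random range of -0.09 to 0.13. Only 2 of its members were detected in both libraries, and its median was 1.065 and 0.15 TPM in the replicate 1 and 2 libraries. Its members include the secreted inhibitor Spink4 at 26.2 and 0.89 TPM in the replicate 1 and 2 libraries, the intestinal transcription factor Cdx1 at 1.93 and 0.14 and the mucin Muc2 at 1.58 and 0.32, while Vil1, which kidney tubules also make, stood at 10.1 and 9.34. The lectin gene Lgals4 of gut epithelium was at 26.4 and 9.7 TPM. Epidermis genes were also higher in replicate 1, with a median difference of -0.25 (6 of 9 members above 0). Only 2 of the 10 were detected in both libraries, and the list median was 0.395 and 0.32 TPM. That shift therefore rests mostly on genes below 1 TPM. Loricrin (Lor) stood at 3.45 and 0.79 TPM, whereas Krt17, at 0.42 and 1.96, went the other way. Cartilage genes had a median difference of -0.24 (9 of 10 higher in replicate 1), but over the 5 members detected in both libraries their median log2 ratio of -0.17 lay inside the random range of -0.20 to 0.31, with Col2a1 at 22.5 and 15.2 and Col10a1, of hypertrophic cartilage, at 1.7 and 0.25 TPM. The exocrine pancreas list did not stand apart, at 0.16 and the 96.5 percentile, although all 9 members above 0 were higher in replicate 2 and Ctrb1 stood at 0.36 and 4.19 TPM. Limb patterning genes on the same measure were at 0.16 and the 95.4 percentile, with 6 of 8 higher in replicate 2.

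Further genes of bone and osteoclasts, picked after their values were seen, were higher in replicate 1. Spp1, osteopontin, which kidney tubules also make, stood at 432 and 52.6 TPM. The osteoclast proteases and phosphatase Ctsk and Acp5 stood at 36.1 and 7.79 and 18.98 and 5.48 TPM, and the osteoblast genes Sp7, Ifitm5 and Runx2 at 4.84 and 1.04, 18.8 and 3.67 and 2.61 and 1.08 TPM. Toward replicate 2, the neuronal genes Stmn3, Nefl and Gap43 stood at 4.17 and 14, 5.02 and 12.8 and 13.9 and 28.8 TPM, the smooth muscle genes Actg2 and Cnn1 at 20.6 and 106 and 5.6 and 23.2, and the liver genes Ahsg and Fga at 8.85 and 26.4 and 4.51 and 9.84.

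The adrenal cortex and medulla lists were higher in replicate 2 by median log2 ratios of 1.60 and 2.44. A separate list of 18 adrenal markers also shifted toward replicate 2, with a median of 0.63 over the 12 members detected in both libraries and 11 of 12 higher there. Scaling or library size moves genes of like abundance together, and the central 95% of random lists matched to that list ran from -0.08 to 0.14, which argues against it. The most abundant of the 18 were Fdx1 at 86.7 and 105 TPM and the aldo-keto reductase Akr1b7 at 50.7 and 130 TPM, and which of them the kidney itself makes was not measured here. A larger share of adrenal tissue in the replicate 2 pool may account for the pattern, and no biological explanation was tested because both pools belong to 1 group.

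Skeletal muscle and bone genes were higher in replicate 1. A separate list of 16 skeletal muscle markers had a median log2 ratio of -0.88, with 14 of 14 detected members higher in replicate 1, led by Myl1 at 89.95 and 42.1 and Mylpf at 67.7 and 40.7 TPM. A list of 12 bone markers had only 2 members detected in both libraries, so all members were used on log2(TPM + 1), and gave a median of -0.55 with 11 of 12 higher in replicate 1; without Panx3, which was among the differing genes, it was -0.51, and its most abundant members were Alpl at 20.8 and 10.4 and Bglap at 4.56 and 0.3 TPM. Muscle and bone in the replicate 1 pool may each account for part of the pattern. For RNA or reads of a limb sample, limb patterning genes gave 0.081 over 4 detected members, at the 63.0 percentile. By the rule first written, a median at or above the middle of random lists counted against a limb sample, and this one did. Under the rule added later the value cannot decide, because the 4 members went both ways. Over all members, 6 of 8 were higher in replicate 2. No biological explanation was tested.

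Smooth muscle genes were higher in replicate 2, and a separate list of 10 gave a median log2 ratio of 0.59 against a random range of -0.12 to 0.12, which argues against scaling or library size. A separate list of 7 urothelium and ureter markers had a median of 0.80, with 5 of 6 detected members higher in replicate 2, among them Krt15 at 4.11 and 12.05 and Upk3b at 3.22 and 7.14 TPM, while Krt7, the most abundant at 58.7 and 54.9 TPM, went the other way. Upk3a, the most abundant gene of the first urothelium list, differed little between the pools. Which other tissues in the pools make these markers was not measured here. More ureter in the replicate 2 pool is a candidate explanation, though Krt7 and Upk3a, the most abundant of their lists, showed no clear rise. Larger blood vessels predict a rise of arterial endothelium genes in replicate 2, which was not seen. Their median was -0.041, inside the random range of -0.11 to 0.17, with 4 of 6 detected members higher in replicate 1. The most abundant were Hey1 at 45.2 and 40.8 and Sox17 at 28.7 and 27.7 TPM. A median below that range was needed to count against larger vessels, so they remain open. No biological explanation was tested.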
